A study of Homo sapiens with 8 samples.

How the data were processed

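Promoter Capture Hi-C was measured in 8 libraries of tamoxifen-resistant MCF7 breast cancer cells (TAMR), 2 replicates in each of 4 groups. Per the labels, control early cells were grown for 11 days, decitabine day 7 cells received 100 nM decitabine on each of 7 days, decitabine recovery cells received the same course and were harvested on day 35, and control late cells were grown for 35 days. The drug-free period of the recovery group is 28 days in the treatment labels and 21 days in the series text, and these sources were not reconciled. Per the labels, the libraries were made with the Arima Hi-C+ kit and a custom SureSelect RNA bait set. The extraction text in the labels speaks of frozen tumour material, although every sample is labelled as the cell line. The labels do not say whether the replicates were separate cultures, so p-values from tests between groups measure only the spread between these samples. Those for gene lists and for enriched windows rest on other spreads, given below.

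The deposited values are raw counts: per the file headers, each line gives the number of read pairs that join a bait fragment to another restriction fragment, without normalization. The other deposited columns hold the fragment numbers, the length of the other fragment in bp and the signed distance in bp between the fragments. Per the file headers, the authors mapped and filtered the reads with HiCUP, used a fragment map of hg38 digested at GATC and GANTC, and wrote the counts in the input layout of CHiCAGO. The submitters' processing notes give hg38 and GRCh38 as the genome builds. The HiCUP version, the aligner and the counting script were not given in the sources used here. Pairs that were not seen are not listed. Whether repeated products were removed before counting was not given in the sources used here.

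The files hold no coordinates, so the fragments were numbered again from an in-silico digest of hg38 at GATC and GANTC (pysam 0.24.0). The numbering was checked against the deposited lengths and distances: in each library between 1 and 8 other-end lengths differed, and no cis distance differed by more than 1 bp. A bait was assigned to a promoter when a GENCODE 44 start site lay within 1000 bp, coding transcripts first. The 94957 bait fragments gave 23931 promoters, of which 22440 carried a gene name. A promoter was called a CpG island promoter when the 500 bp on each side of its start site had at least 50% GC and an observed over expected CpG ratio of at least 0.6, which held for 11055 promoters.

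The listed read pairs per library numbered 21129974 and 15239428 in control early, 26758424 and 20529221 in decitabine day 7, 16274946 and 23073160 in decitabine recovery, and 13764798 and 30588775 in control late. The read pairs at 20 kb to 2 Mb from the bait ranged from 5990011 to 13933746 per library. The common biological coefficient of variation was 0.154 over promoters and 0.177 over promoter windows. Counting intervals (exact Clopper-Pearson, 95%) and floors of 3 reads per library cover counting error only.

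The promoter contact level was the number of cis read pairs 10 kb to 2 Mb from the baits of a promoter, printed as CPM, scaled to 1000000 per library after TMM. Reads to other chromosomes at a promoter were scaled to 1000000 such reads per library, without TMM. Promoters with 10 or more reads in at least 2 libraries were tested, 22349 in all. A promoter window was a promoter and a 10 kb interval 20 kb to 2 Mb away, with at least 40 reads over the 8 libraries and at least 2 times the reads that the promoter's total and the distance gave, which left 86501 windows. Window counts were scaled by the library's total in the same of 20 distance bands, and are printed as reads at the mean of the 8 libraries' totals. Both were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit, glmQLFTest) on a model of the 4 groups without a replicate term, and called at a Benjamini-Hochberg adjusted p under 0.05. The 5 contrasts were decitabine day 7 minus control early, decitabine recovery minus control late, control late minus control early, the difference of both decitabine effects, and their average. Log2 fold changes are given with the standard error implied by the test statistic.

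Enriched windows were counted in each library after thinning to 5990011 reads at 20 kb to 2 Mb, at a Poisson adjusted p under 0.05, which covers only counting error within that library, with at least 5 reads and at least 2-fold enrichment. This count and 12 shares or means of the read pairs were compared between the 4 decitabine and the 4 control libraries by an exact two-sided permutation test of the difference in means, whose smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the 13 measures. The difference of both decitabine effects was tested in the same way, as control early and recovery against day 7 and control late, and by reassigning libraries within each time point (36 ways, smallest possible p 0.0556); both were added after the data had been seen. The exact test of 2 libraries against 2 has a smallest p of 0.333, so the single contrasts of these measures are given as means and spread. A linear fit of the 4 groups with a pooled spread (4 residual degrees of freedom), also added after the data had been seen, can test them, but its p-values are approximate with so few libraries and are not given. Its adjusted p was under 0.05 at day 7 for the shares over 10 kb to 100 kb and 1 Mb to 10 Mb and the mean log10 distance, each kept in 3 of the 8 fits without 1 library, and for the difference of the effects in the first share and the distance, each kept in 0 of 8. Persistence was taken as the correlation, across windows or promoters, of the log2 fold changes at day 7 and at recovery, which share no library.

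The 10 gene lists were fixed before the data were examined: estrogen receptor genes and targets, cancer-testis and germline genes, interferon and viral-sensing genes, imprinted genes, HOX and protocadherin clusters, p53 targets and cell cycle arrest, invasion, EMT and endocrine resistance genes, DNA methylation machinery, basal, stromal and immune cell markers, and housekeeping genes. They were tested on promoter levels with camera of limma 3.58.1 at the preset correlation and with an estimated correlation, adjusted over the 10 lists of a contrast. Camera compares the genes of a list with all other genes. At the preset correlation its p therefore rests on the spread between genes under an assumed correlation. The groups, contrasts, tests, thresholds, lists, naming rule and most alternatives were also set before the data were examined. The naming rule took, in the first 3 contrasts, called promoters or windows whose libraries did not overlap between the groups: the 10 largest rises and falls for promoters, and the 5 largest rises and falls for windows with 1 per promoter. Where fewer than 5 passed, the 5 with the smallest p were taken. For each list it took the members called over all promoters, otherwise the first 2 tested members. ESR1, GREB1, TFF1, PGR, MYC, CCND1, DAZL and H19 were named where tested, and H19 was not tested. Promoters called by DESeq2 at day 7, list members called over the list alone, the called promoters and windows of the average effect, the windows called at day 7 with the promoter offset, and the windows of RPS6KB1, BRIP1, PPM1D and TRIM37 were chosen after their values were seen.

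Alternatives for promoters were median-of-ratios size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, distances of 20 kb to 1 Mb, an offset with the promoter's read pairs to other chromosomes (trans reads), a replicate block, and each library left out in turn. Alternatives for windows were TMM factors, an offset with the promoter's distal total, DESeq2, a minimum of 80 reads, no enrichment filter, windows of 20 kb, a replicate block, and each library left out. Enriched windows were also counted without thinning and at 4-fold. An offset with each library's trend on GC content, its combination with the replicate block, and counts of distinct fragment pairs were added after the data had been seen. In the window tests the distinct pairs were scaled by the distance band totals of all reads, not of distinct pairs. In a fit without 1 library, the lone library of its group was assumed to vary like the other groups. The tests were run on simulated data: with 200 promoters changed at day 7 by 1.5-fold, 2-fold or 4-fold, 8.96%, 67.2% and 95.5% of them were recovered with 5 false calls. For windows the shares were 0%, 7.46% and 33.3% with 1 false call. The simulated counts were drawn independently for each row, without structure shared within libraries. These shares therefore do not measure what the fits of the real data could find. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Read pairs to the mitochondrial genome were left out of the trans reads, and no sample was left out.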

Results

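Promoter Capture Hi-C counts read pairs that join a promoter fragment to any other restriction fragment. It was collected from tamoxifen-resistant MCF7 cells (TAMR), a line derived from estrogen receptor positive MCF7 breast cancer cells by long culture in tamoxifen. The 8 libraries formed 4 groups of 2 replicates: control early, decitabine day 7, decitabine recovery and control late. Decitabine is a cytidine analogue that depletes DNA methyltransferase 1 and lowers DNA methylation in dividing cells. The listed read pairs ranged from 13764798 in control late replicate 1 to 30588775 in control late replicate 2. The series asks how loss of DNA methylation affects the contacts of promoters. All positions are in hg38, genes are those of GENCODE 44, errors after ± are standard deviations over 2 replicates for levels and standard errors for log2 fold changes, and p-values are from edgeR unless another tool is named.

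The first comparison, decitabine day 7 minus control early, asks what differed after 7 days of the drug. Per the labels control early cells were grown for 11 days, so drug and time in culture are not fully separated. The promoters with the smallest p were all higher after the drug, and none passed (adjusted p = 0.261 for each). MIR148A, a microRNA gene (ENSG00000199085.3, chromosome 7, 25949960 to 25950237), had 4.18 ± 0.499 CPM (cis read pairs scaled to 1000000 per library) in control early and 18.8 ± 0.761 in decitabine day 7, a log2 fold change of 2.16 ± 0.27. NPTX2, which encodes a neuronal pentraxin (ENSG00000106236.4, chromosome 7, 98616439 to 98617994), went from 2.59 ± 0.108 to 9.59 ± 0.559, a log2 fold change of 1.88 ± 0.27. The epithelial transcription factor gene KLF5 (ENSG00000102554.14, chromosome 13, 73054274 to 73055669) was higher by 1.75 ± 0.24 on the log2 scale, from 5.22 ± 0.832 to 17.5 ± 2.91. The receptor gene TLR2 (ENSG00000137462.9, chromosome 4, 153683432 to 153685436) was higher by 1.70 ± 0.26, and the tyrosine phosphatase gene PTPRE (ENSG00000132334.17, chromosome 10, 127905951 to 127907535) by 1.65 ± 0.25, from 10.7 ± 0.757 to 33.5 ± 0.443. The promoters' read pairs to other chromosomes, scaled to 1000000 such pairs, were higher as well, from 5.67 ± 0.139 to 20.2 ± 0.486 CPM at MIR148A, from 5.34 ± 1.72 to 13.1 ± 1.06 at KLF5 and from 9.12 ± 0.0502 to 19.7 ± 1.73 at PTPRE. Of 22349 promoters, edgeR called 0 and 2037 had an unadjusted p under 0.05. Without control late replicate 1 edgeR called 2, and 2 without control late replicate 2.

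DESeq2 called 36 promoters at day 7, of which 35 were higher and 1 lower. The smallest of its adjusted p-values belonged to MIR148A (8.9e-06), PTPRE (4.1e-05), KLF5 (5.9e-04), TLR2 (5.9e-04) and the transcription factor gene BHLHE23 (7.3e-04, log2 fold change 1.41 ± 0.27). The developmental genes GATA5 and HOXA13 and the meiotic gene SYCP3 were also higher in DESeq2, by 3.08 ± 0.73, 1.54 ± 0.37 and 1.43 ± 0.35. The imprinted gene FAM50B and the chaperone gene HSP90AB1 were higher by 0.89 ± 0.21 and 0.96 ± 0.21. ACTR6, a chromatin remodelling subunit gene, was the 1 promoter that DESeq2 called lower, by -0.79 ± 0.19 (adjusted p = 0.036). With an offset for reads to other chromosomes edgeR also called 0 promoters, and that offset moved the median of all promoters by -0.13 on the log2 scale.

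**Figure D1:**
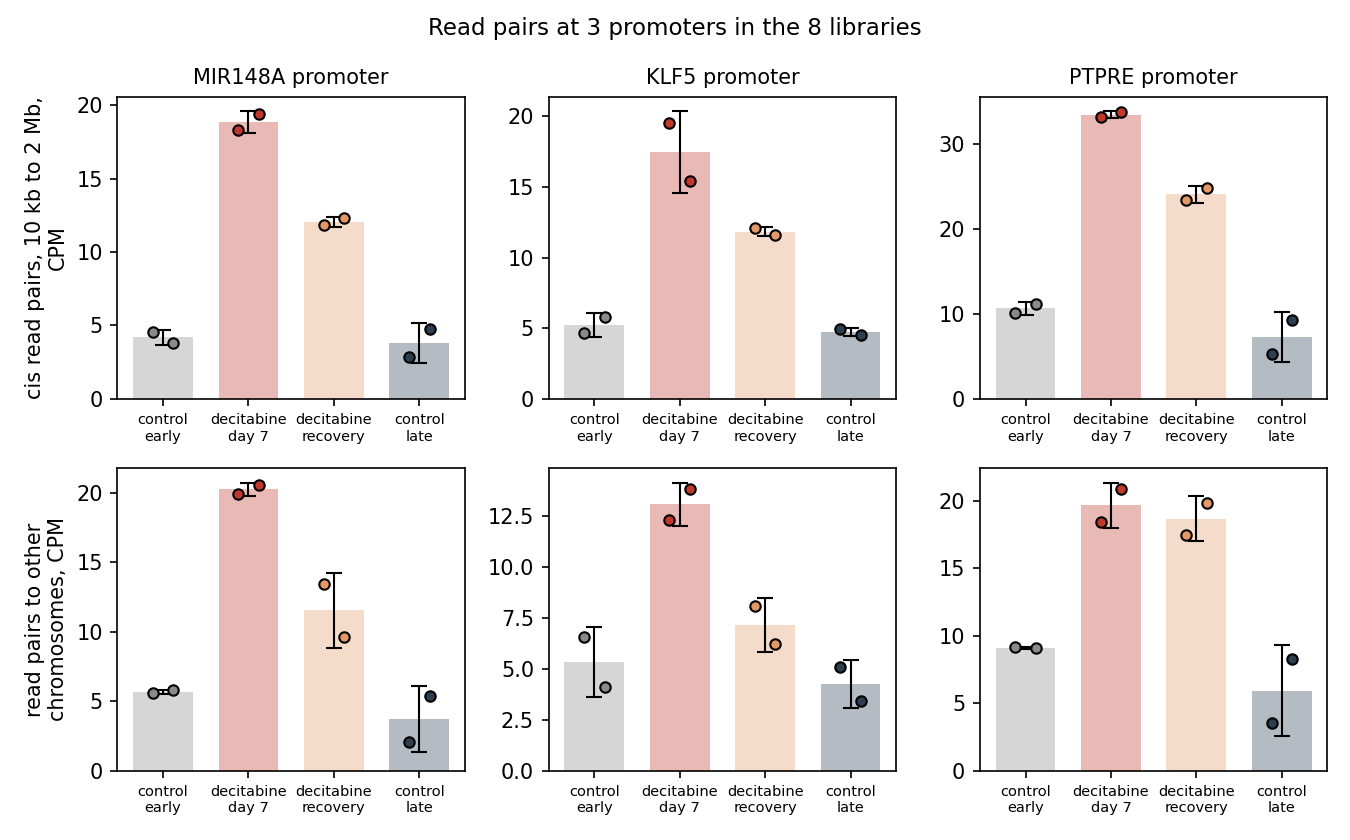
Read pairs in CPM (y axis) at the MIR148A, KLF5 and PTPRE promoters in the 4 groups, upper panels in cis over 10 kb to 2 Mb and lower panels to other chromosomes. Points are libraries, bars are means of 2 and error bars are 1 SD; at MIR148A the means in cis were 4.18, 18.8, 12.1 and 3.80 from left to right.

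Among the fixed gene lists, cancer-testis and germline genes were higher at day 7: 40 of 48 promoters were higher, with a median log2 fold change of 0.28 (camera adjusted p = 1.9e-06, and adjusted p = 0.29 with an estimated correlation). These genes are silenced by promoter methylation in most somatic cells. Imprinted genes were higher at 22 of 29 promoters, with a median of 0.26 (adjusted p = 7.6e-04, and adjusted p = 0.14 with an estimated correlation). HOX and protocadherin genes were higher at 39 of 54 promoters, with a median of 0.14 (adjusted p = 0.00247, and adjusted p = 0.29 with an estimated correlation), but relative to reads to other chromosomes the list was lower (adjusted p = 0.0148). Invasion, EMT and endocrine resistance genes were higher at 23 of 35, with a median of 0.12 (adjusted p = 0.0168, and adjusted p = 0.29 with an estimated correlation). With the offset for reads to other chromosomes the adjusted p was 0.357 for cancer-testis, 0.436 for imprinted and 0.568 for invasion genes. The call of invasion genes was lost without control early replicate 1 (adjusted p = 0.0744), without decitabine day 7 replicate 2 (adjusted p = 0.0842) and with the GC offset (adjusted p = 0.0933, and adjusted p = 0.107 with the replicate block added).

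Single list members that passed at day 7 when adjusted over the list alone were SYCP3 for cancer-testis genes, FAM50B for imprinted genes, and HOXA13 and HOXD9 for HOX and protocadherin genes, that is 1, 1 and 2 promoters, against 0 over all promoters. The other lists did not pass: estrogen receptor genes and targets had 29 of 52 higher (adjusted p = 0.603), interferon and viral-sensing genes 19 of 50 (0.0792), p53 targets 10 of 31 (0.196), DNA methylation machinery 16 of 26 (0.782), basal, stromal and immune markers 16 of 28 (0.603) and housekeeping genes 12 of 28 (0.108). With the GC offset p53 targets (adjusted p = 0.0253) and housekeeping genes (adjusted p = 0.0235) passed as lower. No member of these 6 lists passed when adjusted over the list alone. The estrogen receptor gene ESR1 (chromosome 6, 151656199 to 151657675) had 105 ± 7.88 and 86.9 ± 2.99 CPM, a log2 fold change of -0.27 ± 0.14 (adjusted p = 0.609). Its targets GREB1, TFF1 and PGR had 0.30 ± 0.14, 0.05 ± 0.14 and -0.42 ± 0.22, and the growth genes MYC and CCND1 -0.19 ± 0.12 and -0.06 ± 0.20, none passing. The first members of the remaining lists did not pass either: DAZL 0.21 ± 0.29, MAEL 0.20 ± 0.31, IFI27 0.19 ± 0.24, IFI44 -0.06 ± 0.15, IGF2 0.54 ± 0.22, KCNQ1 1.15 ± 0.38, HOXA1 0.16 ± 0.29, HOXA2 0.12 ± 0.17, CDKN1A 0.07 ± 0.18, MDM2 -0.33 ± 0.13, VIM -0.03 ± 0.19, ZEB1 -0.01 ± 0.14, DNMT1 0.38 ± 0.21, DNMT3A 0.14 ± 0.15, KRT5 0.28 ± 0.20, KRT17 1.31 ± 0.55, ACTB 0.11 ± 0.18 and GAPDH 0.12 ± 0.15.

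**Figure D2:**
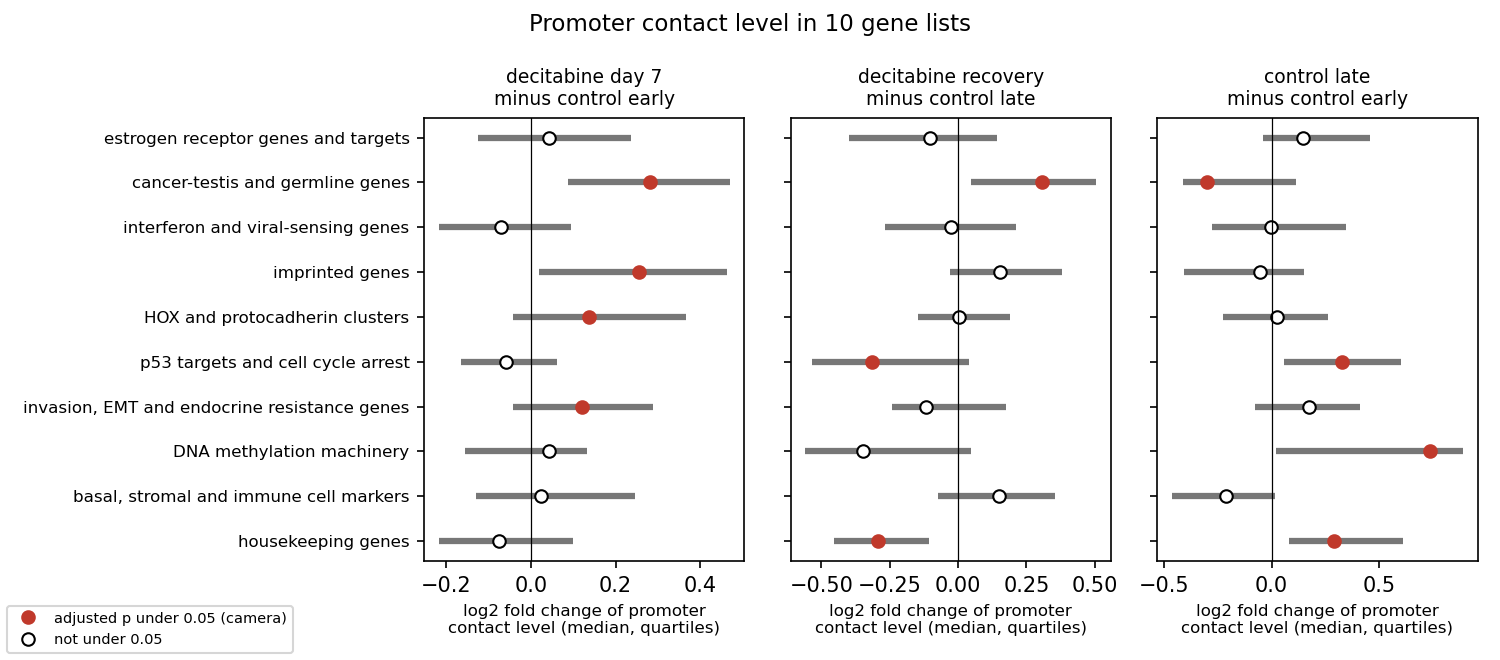
Median log2 fold change of the promoter contact level (x axis; line, quartiles over the genes of a list) for 10 gene lists (y axis) in 3 comparisons; filled points had a camera adjusted p under 0.05 at the preset correlation. Cancer-testis and germline genes had medians of 0.28 at day 7, 0.31 at recovery and -0.30 between the control groups.

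At the level of single contacts, 20 of the 100 day 7 windows with the smallest p were higher, but 57 of 100 with TMM factors, so their direction depends on the scaling, and none passed (adjusted p = 0.349 for the first 5). The MIR21 promoter and the window at the TRIM37 start site 735.5 kb away (chromosome 17, 59100001 to 59110000) had 832 ± 113 normalised reads in control early and 495 ± 88.1 in decitabine day 7, a log2 fold change of -0.75 ± 0.16. MIR21 is a microRNA gene often amplified with its neighbours in MCF7 cells. The C3orf49 promoter and a window inside SYNPR (chromosome 3, 63340001 to 63350000) had -1.05 ± 0.22, and the CATSPERB promoter and a window in the same gene (chromosome 14, 91650001 to 91660000) -1.68 ± 0.35. RNU6-283P and the POU5F1 start site (chromosome 6, 31180001 to 31190000) had -2.72 ± 0.60, whereas SCARA5 and a window in its own gene (chromosome 8, 27860001 to 27870000) had 2.74 ± 0.61. The most read windows of receptor pathway genes and of the germline gene DAZL did not pass: ESR1 with a window in CCDC170 had -0.28 ± 0.33, PGR -0.06 ± 0.53, TFF1 0.72 ± 0.48, MYC -0.20 ± 0.25, CCND1 -0.30 ± 0.27 and DAZL 0.80 ± 0.65, and GREB1 had no tested window. Of 86501 windows, edgeR called 0, with 5932 at an unadjusted p under 0.05, and DESeq2 called 0, with 1448. The median of all windows was -0.14 on the log2 scale, and 0.01 with TMM factors.

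Relative to each promoter's own distal total, with which 42.3% of all windows were higher at day 7, edgeR called 14 windows, all lower. They held MIR21 with 2 windows at TRIM37 (-0.75 ± 0.09, adjusted p = 8e-11, and -0.72 ± 0.09, adjusted p = 3.6e-08) and ZMYND8 with a window in its own gene (-0.51 ± 0.08, adjusted p = 3.6e-05). MTMR4, RAD51C and U3 each contacted a window at TEX14 less (-1.33 ± 0.23, -0.49 ± 0.10 and -0.41 ± 0.08), and TRIM37 a window at VMP1 (-0.55 ± 0.11). HOXC6 was lower by -1.06 ± 0.22 at a window 196.3 kb away. C3orf49, FIS1, SLC4A2, STRADA, TBCCD1 and TMEM238 made up the rest, between -2.11 and -0.75.

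Enriched windows were counted after thinning each library to the same number of reads at 20 kb to 2 Mb, which does not equalise the distinct pairs per read. The decitabine day 7 libraries had 18601 ± 268.7 enriched windows and the control early libraries 27849.5 ± 3400 (SD, n = 2), so that the day 7 mean was 66.8% of the control mean and both day 7 libraries lay below both controls. Without thinning the day 7 mean was the higher, 46118.5 against 42723, but at unequal depth. The day 7 libraries had 11784191 and 8797196 reads at 20 kb to 2 Mb, and the control early libraries 9316784 and 6579167. Decitabine recovery had 26030.5 ± 3108 and control late 32705 ± 8383. The mean over all decitabine libraries differed by -7961.5 from that over the control libraries, 22315.8 against 30277.2, which did not pass (exact two-sided permutation test, p = 0.0857, adjusted p = 0.495 over 13 measures, smallest possible 0.0286). The share of cis contacts over 10 kb to 100 kb was 23.5% ± 0.288 at day 7 and 24.5% ± 0.0657 in control early, and the share over 1 Mb to 10 Mb was 12.9% ± 0.245 and 11.9% ± 0.0275. A linear fit of the 4 groups put both differences under an adjusted p of 0.05, kept in 3 of the 8 fits without 1 library. At recovery the first share was 25.5% ± 0.00917 and in control late 24.9% ± 0.291. The other measures between decitabine and control libraries had exact permutation p-values from 0.0857 to 0.771 and adjusted p-values from 0.495 to 0.771. Trans read pairs were 15.4% ± 1.06, 16.8% ± 1.07, 14.1% ± 0.177 and 14.1% ± 0.685 in control early, day 7, recovery and control late. CpG island promoters took 43.3% ± 1.97, 43.6% ± 2.51, 45.6% ± 3.45 and 51.7% ± 5.04 of distal reads in the same order.

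**Figure D3:**
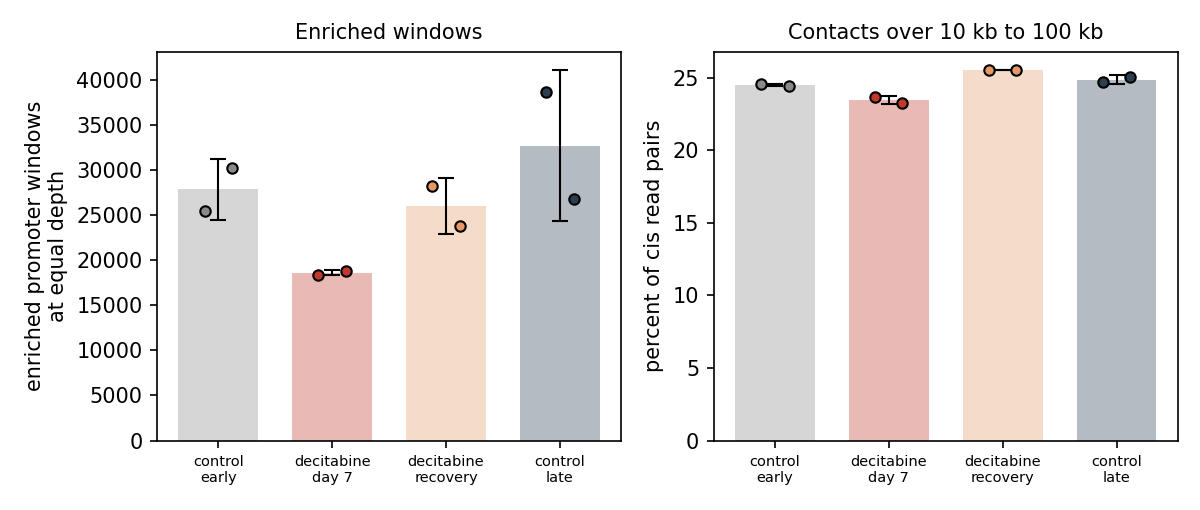
Enriched promoter windows per library at 5990011 reads (left) and percent of cis read pairs over 10 kb to 100 kb (right) in the 4 groups; points are libraries, bars are means of 2 and error bars are 1 SD. The day 7 libraries had 18411 and 18791 enriched windows, and the control early libraries 25445 and 30254.

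The second comparison, decitabine recovery minus control late, asks what remained after the drug-free period. It shares the control late libraries with control late minus control early. A shift of that group would therefore move these contrasts in opposite directions. The promoters with the smallest p again included PTPRE and MIR148A, and none passed (adjusted p = 0.205). PTPRE had 24.1 ± 1.02 CPM at recovery and 7.29 ± 2.9 in control late, a log2 fold change of 1.67 ± 0.25, and MIR148A 12.1 ± 0.334 and 3.80 ± 1.36, a log2 fold change of 1.60 ± 0.27. An unnamed RNA gene (ENSG00000252408.1, chromosome 19, 3519995 to 3521526) was higher by 1.42 ± 0.20, YPEL2 (ENSG00000175155.11, chromosome 17, 59330485 to 59332272) by 1.05 ± 0.16, and the T cell differentiation gene MAL (ENSG00000172005.11, chromosome 2, 95025025 to 95026365) by 1.01 ± 0.18. KLF5 was higher by 1.33 ± 0.25 and TLR2 by 0.90 ± 0.26. Of 22349 promoters edgeR called 0, with 5018 at an unadjusted p under 0.05, and DESeq2 called 348, of which 68 were higher and 280 lower. Without control late replicate 2 edgeR called 5322.

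Cancer-testis and germline genes were higher at recovery at 39 of 48 promoters, with a median of 0.31 (camera adjusted p = 7.1e-04, and adjusted p = 0.65 with an estimated correlation). p53 targets were lower at 23 of 31, with a median of -0.32 (adjusted p = 0.00763, and adjusted p = 0.65 with an estimated correlation), and housekeeping genes were lower at 23 of 28, with a median of -0.29 (adjusted p = 0.00763, and adjusted p = 0.65 with an estimated correlation). Without control late replicate 1 these adjusted p-values were 0.0912 for p53 targets and 0.275 for housekeeping genes, and without decitabine recovery replicate 2 the latter was 0.0572. With the GC offset the medians were 0.30 for cancer-testis genes, -0.15 for p53 targets and -0.23 for housekeeping genes, and both of the latter lost their call (adjusted p = 0.105 each). With the offset for reads to other chromosomes the adjusted p was 0.533 for cancer-testis genes, 0.921 for housekeeping genes and 0.0427 for p53 targets. Imprinted genes had 21 of 29 higher, with a median of 0.15 (adjusted p = 0.0594), and passed with the GC offset (0.27, adjusted p = 0.00192, and adjusted p = 0.00220 with the replicate block added) but not with the offset for reads to other chromosomes (0.385). The other lists without a call were basal, stromal and immune markers (19 of 28 higher, 0.0996), estrogen receptor genes and targets (21 of 52, 0.261), interferon genes (25 of 50, 0.722), HOX and protocadherin genes (28 of 54, 0.722), invasion genes (15 of 35, 0.722) and DNA methylation machinery (7 of 26, 0.0606). For HOX and protocadherin genes the mean, -0.01, had the other sign from the median and the test. The medians of cancer-testis, p53 and housekeeping genes had the opposite sign between the control groups (-0.30, 0.33 and 0.29). How far the recovery values come from the shared control late libraries was not tested. When adjusted over the list alone, 0 members of any list passed at recovery. ESR1 had 0.13 ± 0.14, TFF1 -0.55 ± 0.14, PGR 0.31 ± 0.22, MYC -0.39 ± 0.12, CCND1 -0.45 ± 0.20, GREB1 0.22 ± 0.14 and DAZL 0.65 ± 0.29, none passing.

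Single contacts of 8 promoters fell at recovery against control late, 9 windows in all. All of these promoters but MMP16 also had windows called between the control groups, which share control late. The POP7 promoter and a window in SLC12A9 (chromosome 7, 100850001 to 100860000) had 31.5 ± 0.70 normalised reads at recovery and 108 ± 69 in control late (log2 fold change -1.68 ± 0.31, adjusted p = 0.015). The keratin gene KRT86 and a window in its own body (chromosome 12, 52270001 to 52280000) had 25.3 ± 0.78 and 83.5 ± 29 (-1.66 ± 0.30, adjusted p = 0.014). HEATR6 and the window at the start sites of TUBD1 and RPS6KB1 (chromosome 17, 59890001 to 59900000) fell by 1.52 ± 0.29 (adjusted p = 0.018). The matrix metalloproteinase gene MMP16 and a window without coding genes (chromosome 8, 88540001 to 88550000) fell from 70.8 ± 4.8 to 24.6 ± 0.16 (-1.51 ± 0.29, adjusted p = 0.018), and the next window by 1.47 ± 0.27. RNF43, a ubiquitin ligase gene of the WNT pathway, and a window in its own body (chromosome 17, 58380001 to 58390000) fell by 1.47 ± 0.25 (adjusted p = 0.012). CIART, AP4B1 and TRIM37 had 1 falling window each, by -1.39, -1.24 and -1.19. These calls rest on control late replicate 1 and decitabine recovery replicate 2, without each of which edgeR called 0 windows, and it called 524 without control late replicate 2 and 0 relative to the promoter's distal total or with distinct fragment pairs. The distinct pairs were scaled by the totals of all reads. DESeq2 called 0, with 2049 at an unadjusted p under 0.05.

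The third comparison, control late minus control early, asks how the untreated groups of both culture times differed. The promoters with the smallest p were higher in control late, and none passed (adjusted p = 0.0903). ZBTB37, a zinc finger gene (ENSG00000185278.16, chromosome 1, 173867662 to 173869452), had 20.8 ± 2.19 CPM in control early and 59.4 ± 13.0 in control late (log2 fold change 1.50 ± 0.21). COTL1 (chromosome 16, 84617157 to 84618981), NIFK (chromosome 2, 121736308 to 121736993), CCDC82 (chromosome 11, 96389216 to 96389989) and RSPH1 (chromosome 21, 42496204 to 42496989) were higher by 1.26 ± 0.20, 1.21 ± 0.18, 1.18 ± 0.17 and 1.07 ± 0.16. The progesterone receptor gene PGR had -0.69 ± 0.22 (adjusted p = 0.0925), DAZL -0.75 ± 0.29, ESR1 -0.24 ± 0.14, GREB1 -0.16 ± 0.15, TFF1 0.29 ± 0.14, MYC 0.12 ± 0.12 and CCND1 0.44 ± 0.20, none passing. Of 22349 promoters edgeR called 0, with 7942 at an unadjusted p under 0.05, and DESeq2 called 3214, of which 1934 were higher. Without control late replicate 2 edgeR called 8283, and with the offset for reads to other chromosomes 9.

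The DNA methylation machinery was higher in control late at 20 of 26 promoters, with a median of 0.74 (camera adjusted p = 0.00326, and adjusted p = 0.47 with an estimated correlation). Its members UHRF2 (1.15 ± 0.21), DNMT3L (1.23 ± 0.32), RAD21 (1.18 ± 0.37), SMC1A (0.72 ± 0.16), MBD1 and MBD4 passed when adjusted over the list alone, 6 promoters against 0 over all. Housekeeping genes were higher at 25 of 28, with a median of 0.29 (adjusted p = 0.00326, and adjusted p = 0.47 with an estimated correlation), and p53 targets at 25 of 31, with a median of 0.33 (adjusted p = 0.00518, and adjusted p = 0.47 with an estimated correlation). Cancer-testis and germline genes were lower at 34 of 48, with a median of -0.30 (adjusted p = 0.0117, and adjusted p = 0.47 with an estimated correlation). CpG island promoters made up 80.8% of DNA methylation machinery, 82.1% of housekeeping genes and 71.0% of p53 targets. Among cancer-testis genes they were 54.2%, and among all tested promoters 48.1%. Their share of distal reads was 51.7% in control late and 43.3% in control early. Without control late replicate 1 the adjusted p-values were 0.0658 for housekeeping genes, 0.0581 for p53 targets and 0.120 for cancer-testis genes. With the GC offset the medians were 0.42 for DNA methylation machinery, 0.17 for housekeeping genes, 0.16 for p53 targets and -0.24 for cancer-testis genes, with adjusted p-values of 0.0441, 0.0441, 0.130 and 0.00844, so that p53 targets lost their call. When adjusted over the list alone, 4 p53 targets passed (FAS, FDXR, RRM2B and CDKN2B), 2 housekeeping genes (GPI and POLR2A), 10 HOX and protocadherin genes, 8 basal, stromal and immune markers and 1 invasion gene, SOX9, against 0 over all promoters. The lists without a call were basal, stromal and immune markers (21 of 28 lower, adjusted p = 0.0532), estrogen receptor genes (37 of 52 higher, 0.181), invasion genes (24 of 35 higher, 0.184), imprinted genes (14 of 29 higher, 0.362, with a median of -0.06), HOX and protocadherin genes (28 of 54 higher, 0.910) and interferon genes (25 of 50 higher, 0.912). Imprinted genes passed with the GC offset, with a median of -0.30 (adjusted p = 0.0171, and adjusted p = 0.0185 with the replicate block added). For interferon genes the median was -0.003 and the mean and the test were positive.

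Reads in single windows rose around RPS6KB1, the gene of the S6 kinase, in a region of chromosome 17 known to be amplified in MCF7 cells. Chromosome 17 held 49 of the 159 windows called between the control groups, 47 of them higher, and the RPS6KB1 promoter alone 19. Control late replicate 1 also had the highest share of chromosome 17 in its listed reads (6.50%, against 5.89% to 6.07% in the other libraries) and in its trans reads (9.39%, against 8.50% to 8.94%). With distinct fragment pairs, scaled by the totals of all reads, edgeR called 0 of the windows between the control groups, with 7539 at an unadjusted p under 0.05. The contact of the RPS6KB1 promoter with the TRIM37 start site 787.8 kb away (59100001 to 59110000) rose from 73.4 ± 10.0 normalised reads in control early to 236 ± 72.9 in control late, a log2 fold change of 1.65 ± 0.24 (adjusted p = 4.4e-05). Its contact with a window in VMP1 (59830001 to 59840000) rose by 1.58 ± 0.21 (adjusted p = 2.5e-05). The promoters of the helicase gene BRIP1, the phosphatase gene PPM1D and TRIM37 had 5 called windows each. Of the 159 windows, 145 were higher and 14 lower. Relative to the promoter's distal total edgeR called 1 window between the control groups, and 0 of the 159. These windows are therefore not told apart from a change in all distal reads of their promoters.

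**Figure D4:**
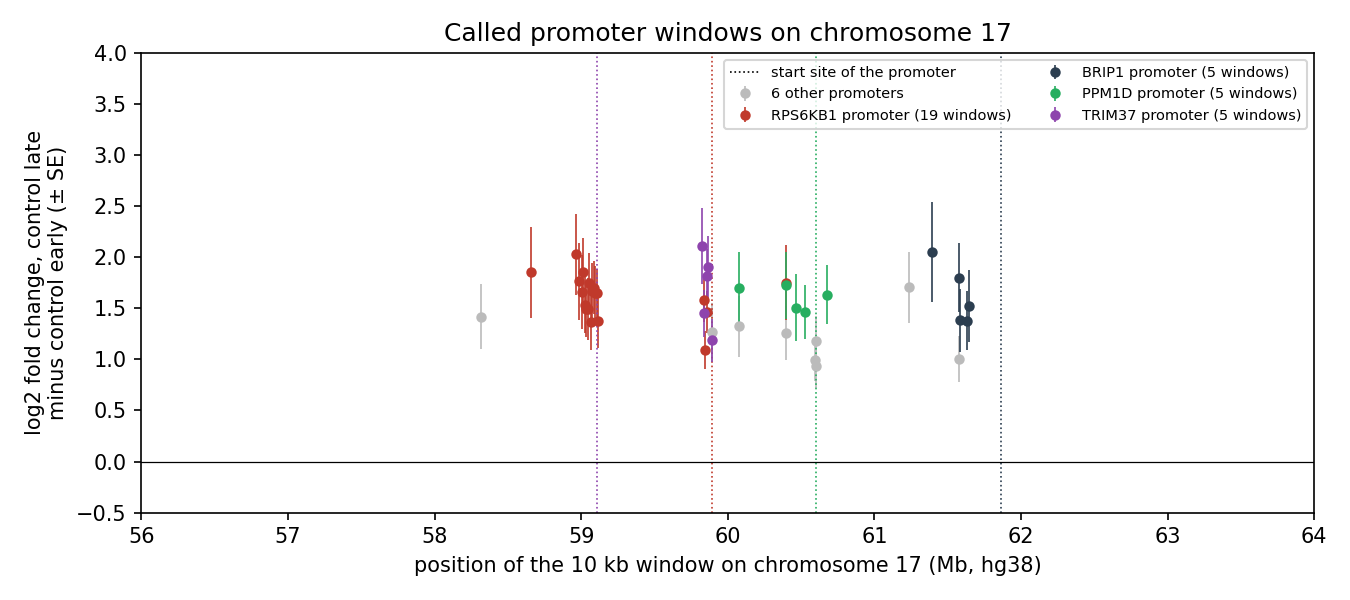
Log2 fold change between control late and control early (y axis, error bars are SE) of the called promoter windows by position on chromosome 17 in Mb (x axis), coloured by promoter, with dotted lines at the start sites. The map holds 43 of the 49 called windows of the chromosome, 19 of them contacts of the RPS6KB1 promoter.

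The largest rises by fold were small contacts. BTF3 and the FCHO2 start site 543.2 kb away (chromosome 5, 72950001 to 72960000) had 0 reads in control early and 26 in control late, at least 3.84-fold higher against the floor of 3 reads per library (adjusted p = 0.011). MKLN1 and a window in its own gene (chromosome 7, 131350001 to 131360000) had 0 and 25 reads, at least 3.02-fold higher (adjusted p = 0.022). FAHD2A and a window in KCNIP3 (chromosome 2, 95300001 to 95310000) had 1 and 32 reads, a ratio of 25.1 with a 95% counting interval from 4.19 to 1020.2 (adjusted p = 0.013). For ARFGEF2 (chromosome 20, 47430001 to 47440000) the ratio was 22.1, from 3.63 to 906, and for GLOD5 and a window in OTUD5 (chromosome X, 48940001 to 48950000) 11.8, from 3.00 to 102. The largest falls were MIR6818 with the CABP7 start site (chromosome 22, 29720001 to 29730000, -3.02 ± 0.67, adjusted p = 0.026) and KCNE5 with the GUCY2F start site (chromosome X, 109480001 to 109490000, -2.76 ± 0.66). The chemokine gene CCL16 and the CCL18 start site (chromosome 17, 36060001 to 36070000) fell by 2.44 ± 0.57, MEPE and a window without coding genes (chromosome 4, 87690001 to 87700000) by 2.40 ± 0.51, and RNU6-283P and the POU5F1 start site by 2.40 ± 0.57 (adjusted p = 0.049). DESeq2 called 45 windows, all among the 159. The count was 3 without control early replicate 1, 48 without control early replicate 2, 3 without control late replicate 1 and 1031 without control late replicate 2, and 1 relative to the promoter's distal total.

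The remaining contrasts ask whether both decitabine effects differed and what they shared. For the average effect, edgeR called 3 promoters, all higher, and 0 with a replicate block, with the offset for reads to other chromosomes or with distinct fragment pairs: MIR148A (1.88 ± 0.19, adjusted p = 0.0392), PTPRE (1.66 ± 0.18, adjusted p = 0.0392) and KLF5 (1.54 ± 0.17, adjusted p = 0.0478). All 4 decitabine libraries lay above all 4 control libraries at each of these promoters. DESeq2 called 199, of which 160 were higher, among them the same 3. The edgeR count was 0 without any 1 of the 6 libraries other than control late, 2 without control late replicate 1 and 2624 without control late replicate 2. For the difference of the effects edgeR called 0 promoters, with 2427 at an unadjusted p under 0.05, and DESeq2 called 0.

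Windows with a higher average contact after decitabine included a contact of PTPRE (chromosome 10, 128000001 to 128010000, 2.52 ± 0.49, adjusted p = 0.014), SCARA5 in its own gene (2.16 ± 0.44), HSP90AB1 with the CAPN11 start site (1.80 ± 0.36) and 2 windows of the amplified gene ZNF217 (0.70 ± 0.13 each, adjusted p = 0.0086). Windows with a lower average contact included SMIM27 with the start site of RIGI, a sensor of viral RNA (-1.95 ± 0.36, adjusted p = 0.0086), RBM25 with ZFYVE1 (-1.33 ± 0.24), MMP16 (-1.11 ± 0.19), ERCC1 (-1.04 ± 0.20) and the coactivator gene NCOA3 (-0.80 ± 0.17). In all edgeR called 35 windows, 10 higher and 25 lower, but with TMM factors 21, 12 higher and 9 lower, so the excess of lower windows turns with this scaling. Relative to the promoter's distal total it called 32, 4 higher and 28 lower, which keeps the excess, with 9 of the 35 among them. DESeq2 called 9, all among the 35, and edgeR called 0 with distinct fragment pairs, which were scaled by the totals of all reads. The count was 0 without decitabine day 7 replicate 1 or without decitabine recovery replicate 2, 17 without decitabine day 7 replicate 2, 5 without either control early library, 2 without control late replicate 1 and 417 without control late replicate 2. For the difference edgeR called 0 windows, with 5289 at an unadjusted p under 0.05, and DESeq2 called 0, with 1147. Without control late replicate 2 edgeR called 3.

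In the average effect cancer-testis and germline genes were higher at 44 of 48 promoters, with a median of 0.25 (camera adjusted p = 4e-08, and adjusted p = 0.46 with an estimated correlation). DDX4, SYCP3, PIWIL1, MAGEB2, STK31, RPL10L, SLC25A31 and TUBA3C passed when adjusted over the list alone, 8 promoters against 0 over all. Imprinted genes were higher at 23 of 29, with a median of 0.26 (adjusted p = 7.3e-04, and adjusted p = 0.13 with an estimated correlation), with 7 passing when adjusted over the list alone (KCNQ1, SNRPN, GNAS, DLK1, MEG3, INPP5F and FAM50B). p53 targets were lower at 24 of 31 (adjusted p = 0.00336, and adjusted p = 0.53 with an estimated correlation) and housekeeping genes at 23 of 28 (adjusted p = 0.00273, and adjusted p = 0.53 with an estimated correlation). With the offset for reads to other chromosomes these 4 calls were lost (adjusted p = 0.177 for cancer-testis genes, 0.112 for imprinted genes, 0.112 for p53 targets and 0.177 for housekeeping genes). For housekeeping genes the adjusted p was also 0.0512 without control late replicate 1. HOX and protocadherin genes were higher at 37 of 54 in the average effect (camera adjusted p = 0.0605), and passed with the GC offset (adjusted p = 0.0389). Of these, HOXA5, HOXA7, HOXA13 and HOXD9 passed when adjusted over the list alone. For the difference of the effects no list passed, and the smallest adjusted p was 0.196. Over the list alone, SOX9 of the invasion genes and THY1 and CD14 of the basal, stromal and immune markers passed for the difference. None of the calls of lists in any contrast held with an estimated correlation.

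Persistence asks whether the day 7 changes were still there at recovery. Across 86501 windows the correlation of both sets of log2 fold changes was 0.0742 (Pearson) and 0.0750 (Spearman), and across 22349 promoters 0.109 and 0.0789; windows and promoters are not independent replicates, so no p is given. At day 7 edgeR called 0 windows and 0 promoters; of the 14 windows it called relative to the promoter's distal total 11 kept their sign at recovery, and with 20 kb windows 1 of 1. Of the 100 windows with the smallest p at day 7, 69 kept their sign, and 75 with TMM factors, against 53.3% and 52.9% of all windows. Of the 100 promoters with the smallest p at day 7, 98 were higher then, and 84 of the 100 kept their sign at recovery, with a median log2 fold change of 1.06 at day 7 and 0.34 at recovery. Over all promoters 49.0% were higher at day 7 and 52.0% kept their sign. With the offset for reads to other chromosomes, 4 of its 100 promoters with the smallest p were higher at day 7, with a median of -0.66, and 44 kept their sign. Over all promoters 30.7% were higher at day 7 with that offset and 47.7% kept their sign, so part of this turn is a shift of all promoters. Of the 36 promoters that DESeq2 called at day 7, 29 had the same sign at recovery. Without decitabine day 7 replicate 1 the Pearson correlation was -0.00450 across windows and -0.173 across promoters, without decitabine day 7 replicate 2 it was 0.131 and 0.427, and without control early replicate 2 0.0156 and -0.102. Across promoters it was 0.287 without control early replicate 1, -0.0170 with the offset for reads to other chromosomes and 0.266 with the GC offset.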

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

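The tests of restriction digestion at day 7, of copy number and of the CpG island share of trans reads were set before their results were seen, and the tests of the difference of the effects, of GC content of the promoters, of digestion at recovery, of chance at recovery, of repeated products, of random ligation and of time in culture were chosen only after the result was seen.

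The share of cis contacts over 10 kb to 100 kb differed in opposite directions between decitabine and control libraries at the 2 time points. It was lower by -1.05 percentage points in decitabine day 7 than in control early and higher by 0.645 points in decitabine recovery than in control late. Both libraries of each decitabine group lay outside both of their controls. The difference between these effects, 1.70 points, stays undecided. An exact two-sided permutation test of 4 libraries against 4 gave p = 0.171 (adjusted p = 0.825 over 13 measures, smallest possible 0.0286), but differences by time and drug widen what it allows by chance. With the libraries reassigned within each time point the exact two-sided permutation p was 0.0556, the smallest that the 36 reassignments allow. A linear fit of the 4 groups, whose p-values are approximate with 2 libraries per group and are not given, put this difference under an adjusted p of 0.05, but in none of the 8 fits without 1 library.

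Enriched windows were fewer at day 7 after thinning, at 66.8% of the control early mean. Without thinning the day 7 mean was 107.9% of it, but there the day 7 library of each replicate number was the deeper one. Repeated sequencing of the same ligation products, as the whole cause, was argued against: with each fragment pair counted once, 1.10 of the log ratio was left (0.987 to 1.30 over the 4 pairings of libraries). Random ligation, which adds few contacts over 100 kb to 1 Mb, stays open: that share was 0.675 points higher in the lower day 7 library than in the higher control early library, but the replicates of control late differed by 1.20 points. A first form of this test compared the factors beyond 10 Mb with those at 1 Mb to 10 Mb and gave ratios of 0.915 to 0.982 over the 4 pairings of libraries, 3 of them below the 0.964 that the replicates allow. A looser contact structure under the drug stays a candidate explanation and was not tested.

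The promoters higher after decitabine were the 35 that DESeq2 called higher at day 7, with a median log2 fold change of 1.14. A GC trend shared by all promoters was argued against: the GC offset left 0.931 of the median (bootstrap interval 0.887 to 1.00). The offset removes only such a trend. Copy number was argued against as well, since 489 promoters nearby had 0.131 of the median (0.0655 to 0.198). The bootstrap intervals resample promoters chosen at day 7 and cover no error between libraries. Blocked digestion at methylated GANTC sites, as the whole cause at day 7, was argued against. Fragments without a CpG at such an end rose by 0.904 of the median of all fragments (0.743 to 0.994). That median includes them, and the promoters were chosen for their day 7 rise. Fragments without such a CpG had a median log2 fold change of 0.977 and those with one 1.35. Within the 20 promoters that hold both kinds, fragments with one exceeded the others by a median of 0.25 at day 7 (13 of 20 positive, against 0.04 in other promoters), so digestion may add to the day 7 rise. At recovery this median was 0.773 (0.214 to 1.28, 17 of 20 positive, against 0.0510 in other promoters), so digestion may account for the recovery signal. Chance stays open. Of the 100 promoters with the smallest p among those that rose at day 7, 84 were higher at recovery, and random sets gave 30 to 59. The random sets were matched on mean reads only and treat promoters as independent, so they do not measure chance between libraries. CpG island promoters made up 67 of the 100, against 48.1% of all tested. With the offset for reads to other chromosomes, 44 of its 100 promoters with the smallest p kept their sign, against 47.7% of all promoters. Removal of methylation that opens these promoters, and so yields more reads both in cis and to other chromosomes, could explain the day 7 values and was not tested, as the files hold no methylation.

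Control late replicate 1 stood apart from the other libraries in the share of CpG island promoters, at 55.3% of distal reads against 41.8% to 48.2% elsewhere. A GC bias of this library is a candidate explanation, because its share of trans reads, which no specific contact sets, was also the highest, by 5.73 points. Change over the culture period stays open, since control late replicate 2 lay 3.43 points above the higher control early library but 7.13 points below replicate 1. The library also had the most enriched windows, 38633. Most windows called between the control groups were lost without this library, and also without control early replicate 1. Without control late replicate 2 far more were called, in a fit that leaves out the spread within control late. Across promoters that spread was the largest of the 4 groups (chi-square per degree of freedom between replicates 16.5, against 4.96 to 9.23). The calls between the control groups therefore lean on control late replicate 1. The calls of DNA methylation machinery between the control groups and of cancer-testis genes at recovery held without it (adjusted p = 0.00533 and 0.00628), though with all libraries both were lost with an estimated correlation (adjusted p = 0.473 and 0.654).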

How the results depend on the processing

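The GC offset, its combination with the replicate block, the counts of distinct fragment pairs, the exact tests of the difference of the effects, the linear fit of shares and means and the persistence across promoters were chosen only after the result was seen; the other alternatives were planned.

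Promoter counts by edgeR were 0, 0, 0, 0 and 3 for day 7, recovery, control late minus control early, the difference and the average effect. With DESeq2 they were 36, 348, 3214, 0 and 199. With the trans reads offset recovery had 1, control late minus control early 9 and the average effect 0. The average effect had 8 without a filter on low counts, 7 with the GC offset and 0 with distinct fragment pairs. Leaving out 1 library gave 0 to 2 at day 7 (2 without control late replicate 1 and 2 without replicate 2), 0 to 5322 at recovery, 0 to 8283 for control late minus control early and 0 to 2624 for the average effect, and each of the 3 highest came without control late replicate 2. The cause was not tested.

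Window counts by edgeR were 0, 9, 159, 0 and 35 in the same order. The promoter distal total offset gave 14, 0, 1, 6 and 32 (4 higher and 28 lower), and 20 kb windows gave 1 at day 7 and 4 at recovery. DESeq2 gave 0 at recovery, 45 for control late minus control early and 9 for the average, and a minimum of 80 reads gave 18, 255 and 75, where fewer windows were tested. TMM factors gave 94 for control late minus control early and 21 for the average, of which 12 were higher, against 10 of 35. Without the enrichment filter recovery and the average effect had 18 each. With distinct fragment pairs recovery, control late minus control early and the average effect had 0 each. These pairs were scaled by the totals of all reads, which does not match the counts. Reads per listed pair were 1.38 and 1.40 in control late and 1.27 to 1.33 in the other libraries. Leaving out 1 library gave 0 to 524 at recovery, 3 to 1031 for control late minus control early, 0 to 3 for the difference and 0 to 417 for the average, each highest without control late replicate 2. The cause was not tested.

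With replicate number as a block, promoters of the average effect numbered 0, also together with the GC offset (0), and its windows 23, while windows at recovery numbered 9 and those of control late minus control early 152. The deviations of the replicates correlated across promoters by 0.610 between control early and day 7 and by 0.733 between recovery and control late, and by -0.598 to -0.485 between the other pairs of groups. Replicate numbers therefore do not pair the samples of all groups alike, but the deviations went together within each time point. The main fits ignore this. The block was 1 term shared by the 4 groups and cannot follow opposite signs, so it is no test with pairing within time points.

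List calls were lost with an estimated correlation. At day 7 the adjusted p was then 0.293 for cancer-testis, HOX and protocadherin, and invasion genes and 0.141 for imprinted genes. At recovery it was 0.654 for cancer-testis genes, p53 targets and housekeeping genes. Between the control groups it was 0.473 for cancer-testis genes, p53 targets, DNA methylation machinery and housekeeping genes. For imprinted genes the estimated correlation was 0.00208 at day 7 and -0.00413 for the average effect, below the preset. A higher correlation between genes therefore does not account for the loss of their call. In the other lists the estimate lay above the preset. With the trans reads offset the adjusted p at day 7 was 0.357 for cancer-testis, 0.436 for imprinted and 0.568 for invasion genes, and HOX and protocadherin genes reversed (0.0148). At recovery it was 0.533 for cancer-testis and 0.921 for housekeeping genes. With the GC offset, and with the GC offset and replicate block, it was 0.0933 and 0.107 for invasion genes at day 7, 0.105 and 0.0932 for both p53 targets and housekeeping genes at recovery, and 0.130 and 0.0963 for p53 targets between the control groups. The cause was not tested. Leaving out 1 library gave adjusted p from 0.0153 to 0.0842 for invasion genes at day 7, from 0.00254 to 0.0912 for p53 targets and from 0.00254 to 0.275 for housekeeping genes at recovery. Between the control groups it gave 0.00267 to 0.120 for cancer-testis genes, 0.00267 to 0.0581 for p53 targets and 0.00267 to 0.0658 for housekeeping genes. Each highest value came without control late replicate 1, except that of invasion genes, without decitabine day 7 replicate 2.

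Persistence across windows was 0.0742, and 0.0816 with TMM factors. Without 1 library it ran from -0.00450 (without decitabine day 7 replicate 1) to 0.131 (without decitabine day 7 replicate 2), and it was 0.0156 without control early replicate 2. Across promoters it was 0.109, from -0.173 to 0.427 without the same libraries, -0.102 without control early replicate 2, 0.287 without control early replicate 1, -0.0170 with the trans reads offset and 0.266 with the GC offset. The cause was not tested.

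Differences in the 12 shares and means and in enriched windows between decitabine and control libraries kept their direction without replicate 1 and without replicate 2. Enriched windows differed by -6602.75 without thinning, -5850 at 4-fold and -3431 with distinct pairs. Without thinning, at unequal depth, the difference turned to 2479 without replicate 2, and day 7 had more than control early (46118.5 against 42723). Of the lists that had not passed, 18 list and setting pairs now passed (among them, with the GC offset, imprinted genes at recovery and between the control groups, and p53 targets and housekeeping genes at day 7), 198 stayed and 31 moved. Of the named promoters and windows, 188 lost their call, 51 gained one, 201 moved and 1768 stayed. In simulated data 7.46% of windows changed by 2-fold were recovered, against 67.2% of promoters. Windows and promoters differ in depth, number and spread, and which of these limits the windows was not tested.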

Other observations

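The counts over other splits of the libraries and over reassignments within the time points were chosen only after the result was seen.

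Beyond the promoters already described, the set called by DESeq2 at day 7 held the glycosyltransferase gene B3GNT7 (1.76 ± 0.38, from 3.69 ± 0.36 to 12.6 ± 0.11 CPM), the receptor gene MRGPRF (1.50 ± 0.31), the zinc finger gene ZNF300 (1.24 ± 0.26) and the NAD synthesis gene NAPRT (1.18 ± 0.26). The RAS effector gene RASSF5 had 1.01 ± 0.25 and the caveolar gene CAVIN3 1.12 ± 0.27. At recovery NAPRT had 1.08 ± 0.23 and MRGPRF 1.09 ± 0.23 in edgeR, while the ghrelin receptor gene GHSR had -0.09 ± 0.18 and the growth factor gene GDF7 -0.03 ± 0.17, after 0.96 and 0.92 at day 7. Of the 35 promoters 21 were CpG island promoters, and 29 were higher at recovery, with a median of 0.48.

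Outside chromosome 17, 110 windows at 88 promoters were called between control early and control late, 74 of them as the single called window of a promoter and 18 at 5 promoters with 3 or more. HOXC13 had 4 windows that rose, between 72.75 kb and 144 kb away on chromosome 12, from 1.27 ± 0.28 to 1.57 ± 0.29 (smallest adjusted p = 0.0028), in an interval without coding genes. The phosphatase gene DUSP1 had 3 windows in ERGIC1 on chromosome 5, 1 of them at its start site (1.85 ± 0.40). PARD6B, a cell polarity gene on chromosome 20, had 3, with 1 at the BCAS4 start site (1.15 ± 0.25), and POP7 on chromosome 7 had 4, with the ACHE start site at 2.68 ± 0.53. AP4B1 on chromosome 1 had 4 windows over PTPN22, RSBN1 and HIPK1, from 1.00 ± 0.19 to 1.40 ± 0.30. Chromosome 7 held 18 and chromosome 12 held 11 of the 159 called windows, and 3 of these called windows remained called without control late replicate 1.

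For the average decitabine effect on promoters, a fit with 2 groups called 0 promoters in the real split of the libraries into 4 and 4, so that all 35 of 35 splits called as many or more by construction and decide nothing about chance; the highest other called 2532. For windows the real split called 1 in that fit, 5 of the 35 splits called as many or more and the highest other 630, so chance cannot be excluded there. In the fit with 4 groups, the 18 reassignments of the libraries within each time point are too few for a share under 0.05: the real one called 3 promoters and 35 windows, and the highest other 0 and 0, so that 1 of the 18 called as many. Splits with many calls may reflect a structure of the libraries other than drug against control, which was not tested. The split of control early and day 7 against recovery and control late, which follows the harvest time, called 74 windows. The first principal component of promoter levels took 69.5% of the variance and set control late replicate 1 (81.8) apart from the other libraries (-38.5 to 19.7).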
